A study of Drosophila melanogaster with 5 samples.

How the data were processed

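The series measured small RNAs in ovaries of 5 Drosophila melanogaster libraries: piwi-ctrl (1 library, embryos at 18 °C), white-embKD (2 libraries, embryos at 28 °C) and piwi-embKD (2 libraries, embryos at 28 °C). The flies carried vasa-GAL80[ts] and da-GAL4 with a short hairpin RNA against piwi (piwi-ctrl and piwi-embKD) or white (white-embKD), per the labels. GAL80[ts] is a temperature-sensitive repressor of GAL4, the driver of the hairpins. Small RNAs were purified by anion exchange and size-selected on a gel, and the libraries were cloned at the Donnelly sequencing centre (piwi-ctrl 1, white-embKD 1, piwi-embKD 1) or at BGI (white-embKD 2, piwi-embKD 2), per the labels' protocols. Titles of the first knockdown libraries carry no number, and they were taken as replicate 1 beside the libraries numbered 2. No label says that the libraries came from separate crosses or cohorts, so p-values measure only the spread between these libraries, which may be partly technical.

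The deposited values are read counts per distinct sequence, in 1 list of 21 nt and 1 of 23-30 nt per library, per the file headers, and they are neither normalised nor pooled. The submitters' processing notes name Bowtie2 (version not given in the sources used here) and the build dm3, with no role for either. How mismatches, repeated placements and structural RNAs were handled is not given in the sources used here. The 23-30 nt list of white-embKD 2 was found to be a concatenation of 21 blocks: its own list first and again last, and between them the other lists of the series and blocks of marker lines. Its first block alone (526002 sequences, 19145652 reads) was used. Sequences with an undetermined base were dropped, from 0.0658% of reads in piwi-embKD 1 to 0.258% in white-embKD 2. The lists hold length classes, not whole libraries, so the library size in every test was the total of 23-30 nt (or 21 nt) reads used, and values are relative to that class.

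Complexity differed by centre. At 3410837 reads, the smallest depth, the Donnelly libraries held 882764 to 983168 distinct sequences, and white-embKD 2 and piwi-embKD 2 held 368267 and 324678. Reads per distinct sequence were 4.10, 3.57 and 6.28 in piwi-ctrl 1, white-embKD 1 and piwi-embKD 1, against 38.3 and 37.3 in white-embKD 2 and piwi-embKD 2. Reads carried no molecular identifiers, so repeated reads cannot be told from repeated molecules.

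No genome sequence was used here. The tests planned on clusters, transposon families, genome windows and genes, the lists fixed for them (germline and somatic transposons, follicle cell piRNA genes, siRNA loci, RNA quality and testis genes) and the check of the targeted gene need placed reads and were not run. The plan made before the data were examined named a test of distinct 23-30 nt sequences for this case, with at least 10 reads in at least 2 libraries: 176919 of 4248613 sequences passed. After the data were seen, contigs were added to give loci back. All k-mers of 18 nt from 23-30 nt reads with a mean weight of at least 0.2 RPM (libraries weighted equally) in at least 2 libraries were extended greedily, and contigs of at least 100 nt were kept. This gave 1671 contigs with a total of 301751 nt (median 141, longest 1701), on which 54.1% to 62.6% of reads of each library were placed. A read was placed where all of its k-mers lay in line on 1 contig. Values per library are given as RPM, relative to the 23-30 nt reads used. A contig is both-strand when its minor strand holds at least 20% of the reads. Both strands of a repeated element from different genomic copies fall together in a contig, so a both-strand contig is not the same as a dual-strand genomic cluster.

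Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with all 5 libraries and 3 groups in a fit, without a block as fixed in the design, and with the replicate number as a block. The numbers pair the samples because the labels tie them to the sequencing centre. Across contigs, the deviations of same-numbered libraries from their group means had a correlation of 0.793, and the log2 ratios of the pairs had a correlation of 0.628, with the same sign in 1255 of 1671 contigs (75.1%). The common biological coefficient of variation of contigs was 0.513 without the block and 0.227 with it, with 2 and 1 residual degrees of freedom. For sequences with the block, edgeR found no spread between sequences beyond the common trend, so that all of them were given the variance of the trend (infinite prior degrees of freedom) and a sequence with uneven counts got no wider error. Alternatives were TMM factors, DESeq2 1.42.0, no low-count filter, each library left out (piwi-ctrl 1 in the blocked fit, the knockdown libraries in the fit without the block), distinct sequences in place of reads, k-mers of 20 nt, a k-mer weight of 0.5 and contigs of at least 200 nt. Strand classes were tested with camera and fry (limma 3.58.1). Values per library (1U, 10A, length, the 10 nt overlap of ping-pong, phasing, the 19 nt duplex of siRNAs) were compared with exact permutation tests on libraries thinned to equal depth where depth matters. The permutations ignored the pairing by centre, so the gap between centres counts as spread in these tests. Values of single libraries on a log2 scale used RPM plus 0.5. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 did the rest. Floors are 3 reads per library, and intervals are exact binomial ones at 95%.

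The rule for named features was fixed for clusters and transposon families and carried over to contigs and sequences after the data were seen. It takes the 10 most abundant contigs, the 10 largest rises and 10 largest falls past the threshold that moved the same way in both pairs, and the 5 smallest p-values of the fit without the block. It named 31 contigs and 21 sequences.

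Before the fits were run, they were tried on simulated data. Counts were simulated from the real ones with the centre effect and the spread of the blocked fit. They follow the blocked model by construction, so the recoveries cannot show which fit suits the real data. For piwi-embKD against white-embKD over 1671 contigs, with 200 changed, the fit without the block recovered 0 of 100 contigs changed 2-fold and 0 of 100 changed 4-fold. The blocked fit recovered 24 and 99 of 100, with 3 false calls. For sequences (120449 tested), the fit without the block recovered 0 at 4-fold and 0 at 16-fold, and the blocked fit 0 of 100 at 4-fold and 16 of 100 at 16-fold, with 0 false calls. The assembly gave 200 contigs for 200 simulated loci, all 200 with the simulated strand class.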

Results

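Small RNAs from Drosophila melanogaster ovaries were sequenced in 5 libraries that fall into 3 groups. In the piwi-embKD group (2 libraries) an inducible short hairpin RNA against piwi was switched on in embryos by a shift to 28 °C, and adult ovaries were sampled. The white-embKD group (2 libraries) received the same treatment with a hairpin against white, an eye colour gene. The piwi-ctrl group (1 library) had the piwi hairpin genotype but was kept at 18 °C, so that depletion was not activated. Piwi is the nuclear Argonaute protein that is guided by PIWI-interacting RNAs (piRNAs) to silence transposons, and the series title states the question: whether embryonic Piwi is needed for dual-strand piRNA clusters, the loci that give piRNAs from both DNA strands, to work in the adult ovary. The deposited lists hold reads of 23-30 nt, the piRNA size class, and of 21 nt, the siRNA size class. The 23-30 nt reads used numbered 4074231 in piwi-ctrl 1, 3410837 in white-embKD 1, 20121226 in piwi-embKD 1, 19096268 in white-embKD 2 and 16056385 in piwi-embKD 2. No genome sequence was used here, so neither transposon families, annotated clusters nor the targeted piwi gene were analysed here. Loci are instead represented by 1671 contigs assembled from the reads themselves, of which 877 carried at least 20% of their reads on the minor strand (both-strand contigs) and 794 did not (one-strand contigs).

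The first comparison, piwi-embKD against white-embKD, asks what embryonic depletion of piwi leaves behind in the adult piRNA population. Within each same-numbered pair, a set of 87 contigs rose and a set of 196 contigs fell in piwi-embKD. The risen contigs went from 3.37% to 7.34% of all 23-30 nt reads in pair 1 and from 4.11% to 9.89% in pair 2. The fallen contigs went from 11.9% to 5.12% in pair 1 and from 11.6% to 5.04% in pair 2. The median log2 ratios of risen contigs were 1.27 and 1.29 in the pairs, and those of fallen contigs -1.25 and -1.23. These calls come from edgeR's quasi-likelihood test with the replicate pair, which is also the sequencing centre, as a block, at a Benjamini-Hochberg adjusted p of 0.05, and "rose" and "fell" are used below for such calls. The sets were called on these same libraries, so the likeness of the pairs follows in part from the choice. Contigs chosen on pair 2 alone, by a log2 ratio beyond 1 or -1, had smaller medians in pair 1. These were 0.87 in pair 1 and 1.37 in pair 2 for 107 higher contigs, and -0.87 and -1.27 for 247 lower ones. The median of all contigs in pair 1 was -0.09. The planned fit had no block, and edgeR then called 0 of 1671 contigs (72 at an unadjusted p of 0.05), while DESeq2 without the block called 44 higher and 44 lower. With TMM scaling in the blocked fit, 188 contigs were higher and 221 lower, so that the higher share of calls went from 30.7% to 46.0%, and the median log2 fold change of all contigs went from -0.13 to 0.00. With contigs of at least 200 nt alone, the blocked fit called 0 of 399 (169 at an unadjusted p of 0.05).

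**Figure D1:**
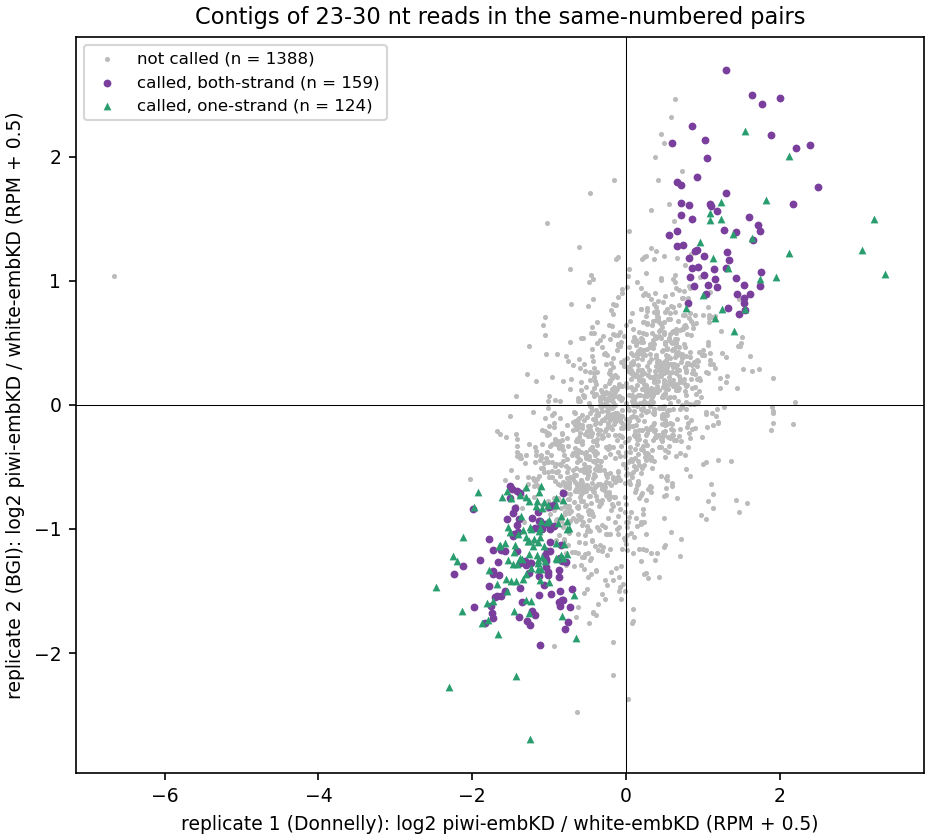
Log2 ratio of piwi-embKD to white-embKD for each of the 1671 contigs in replicate 1 (horizontal axis, Donnelly sequencing centre) and replicate 2 (vertical axis, BGI), from reads-per-million values (RPM) plus 0.5. Grey points were not called by edgeR with the block; called both-strand contigs are purple circles and called one-strand contigs green triangles, and all 283 called contigs lie on the same side of 0 in both pairs.

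The 10 contigs with the largest rises had log2 fold changes of 2.09 to 2.36, and 6 of them were both-strand. Contig 445 (191 nt, 25.4% minor strand, most abundant read TTCCGTCGACTCCAGTAACCGTATGC) went from 103.5 ± 20.3 RPM in white-embKD to 486.6 ± 16.3 RPM in piwi-embKD (mean ± SD, n = 2 each), a log2 fold change of 2.25 ± 0.27 (SE; edgeR with the block, adjusted p = 0.0137). Contig 569 (146 nt, both-strand) rose from 73.2 ± 54.0 to 370.3 ± 310 RPM (n = 2), 2.26 ± 0.28 on the log2 scale, with values of 111 and 590 RPM in pair 1 and 35.0 and 151 RPM in pair 2. Contig 243 (139 nt, 20.02% minor strand) stood at 174.3 ± 48.2 and 733.2 ± 28.9 RPM (n = 2). Contig 9 was the most abundant of the largest rises and came from 1 strand almost alone (0.388% minor strand). Its level was 392 RPM in white-embKD 1 and 3666 RPM in piwi-embKD 1, against 7296 and 20600.1 RPM in the pair from the other centre, and its log2 fold change in the fit without the block, 1.66, turned to -0.07 without piwi-embKD 2 and was 4.95 without white-embKD 2.

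Of the 10 contigs with the largest falls, 7 were one-strand, and their log2 fold changes were -2.31 to -1.78. Contig 861 (114 nt, 11.3% minor strand, most abundant read AGGACCAGGAACCTGAAAAAGGTAC) fell from 299 to 60.3 RPM in pair 1 and from 90.9 to 18.4 RPM in pair 2, a log2 fold change of -2.31 ± 0.29 (SE; edgeR with the block, adjusted p = 0.0137). Contig 72 (246 nt, 0.106% minor strand) went from 2375 ± 1083 to 682.1 ± 346 RPM (n = 2), and contig 995 (116 nt, 5.68% minor strand) from 140.2 ± 24.0 to 36.1 ± 11.6 RPM (n = 2). Of these 10 contigs, only contig 1647 (115 nt, 47.4% minor strand) was also called lower than piwi-ctrl, with 28.2 RPM in piwi-ctrl 1, 17.3 ± 10.7 in white-embKD and 4.38 ± 2.24 in piwi-embKD (n = 2 each).

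**Figure D2:**
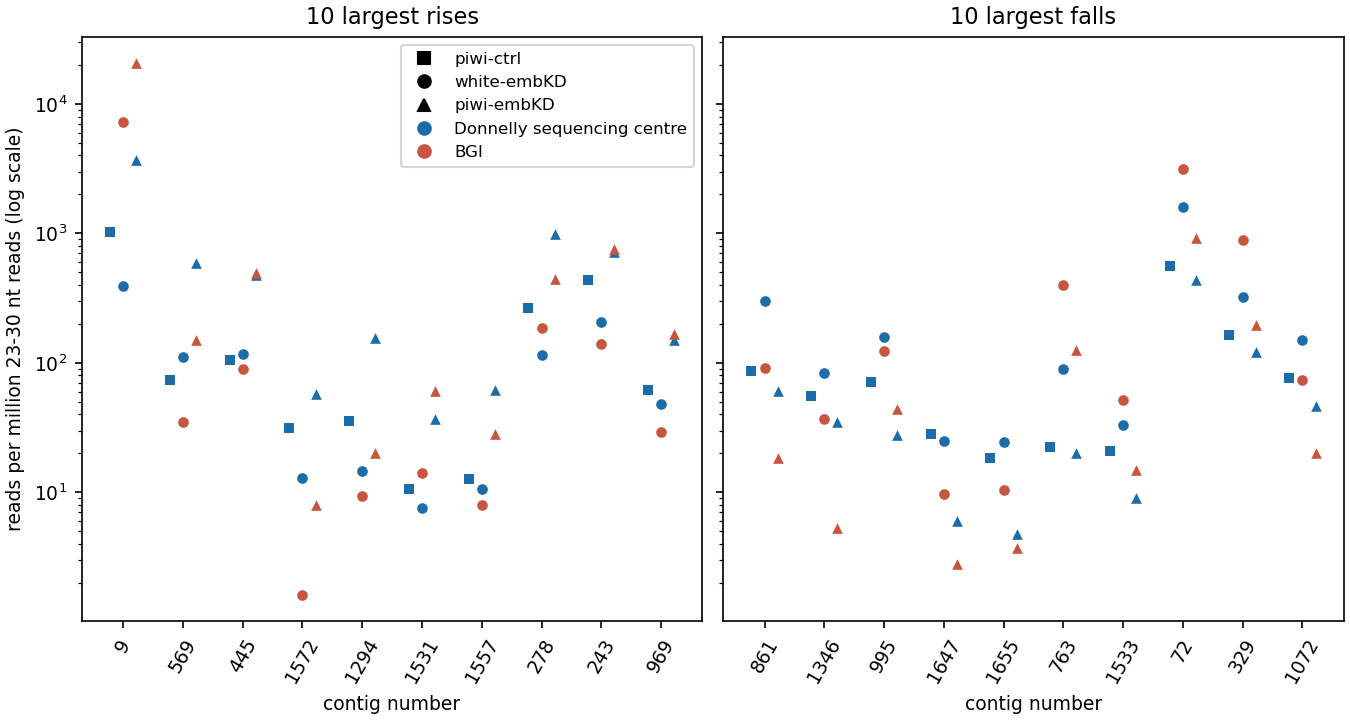
RPM (vertical log axis) in each library for the 10 contigs with the largest rise (left) and the 10 with the largest fall (right) in piwi-embKD against white-embKD with the block, ordered by log2 fold change. Squares are piwi-ctrl, circles white-embKD and triangles piwi-embKD; blue marks the Donnelly sequencing centre and red BGI, and within each colour the triangle lies above the circle on the left and below it on the right.

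Among the 10 most abundant contigs, 3 rose, none fell and 7 passed no threshold in the blocked edgeR fit. With TMM scaling in that fit contigs 2, 6 and 7 also rose (adjusted p = 0.00382, 0.0452 and 0.0487), and with the block and DESeq2 contig 2 did (adjusted p = 0.0143). Contig 3 (1380 nt, 49.2% minor strand) rose from 7508 ± 2139 to 16227.5 ± 7088 RPM and contig 4 (1689 nt, 49.3% minor strand) from 7419 ± 794 to 15135.5 ± 1350.4 RPM (n = 2 each). Their log2 fold changes were 1.07 ± 0.22 and 1.03 ± 0.21 (SE; edgeR with the block, adjusted p = 0.0214 for each). Contig 2, the longest (1701 nt, 36.9% minor strand), had 9681 ± 1193 and 21126 ± 14180.4 RPM in white-embKD and piwi-embKD (n = 2; log2 fold change 0.95 ± 0.31, edgeR with the block, adjusted p = 0.0685). Its log2 ratio was 0.33 in pair 1 and 1.57 in pair 2, so its difference rested mainly on pair 2. Contig 10 (920 nt, 28.5% minor strand) had 6949.7 ± 1439.7 and 5897 ± 1399.8 RPM (n = 2; -0.24 ± 0.21, adjusted p = 0.429), and contig 5 had a log2 fold change of -0.05 ± 0.25 (adjusted p = 0.885), which became 0.08 with TMM scaling in the blocked edgeR fit.

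Both-strand contigs, the nearest stand-in here for dual-strand clusters, showed no rise as a class in piwi-embKD that passed a test. Of the 877, 63 rose and 96 fell, against 24 risen and 100 fallen among the 794 one-strand contigs. The higher share of calls was 39.6% and 19.4% (Fisher's exact test, two-sided, p = 0.000264), and 50.9% and 40.3% with TMM scaling in the blocked fit (Fisher's exact test, p = 0.0368). It was 41.3% and 34.4% when each distinct sequence counted once (Fisher's exact test, p = 0.119). Contigs can share a locus and are not independent units. The median log2 fold change was -0.19 for both-strand and -0.03 for one-strand contigs (camera, p = 0.511 with a preset correlation and p = 0.876 with an estimated correlation). With the block the medians were -0.21 and -0.02 (camera, p = 0.684 with a preset correlation and p = 0.525 with an estimated correlation), and fry, which asks whether the class moved one way on balance and compares it with no other contigs, gave p = 0.0363 for a lower level. This fry p was 0.107 and 0.00294 with minor strand thresholds of 10% and 30%, and 0.668 without the block. Without white-embKD 1 the difference of medians in the fit without the block was 0.02. Summed reads gave another picture. The log2 ratio of both-strand to one-strand reads was -0.47 ± 0.27 in white-embKD and -0.07 ± 0.10 in piwi-embKD (mean ± SD, n = 2; exact permutation test, two-sided, p = 0.333, the smallest that 2 against 2 allow). It was higher in piwi-embKD by 0.28 in pair 1 and 0.53 in pair 2, and the difference of group means, 0.405, was 0.213 without white-embKD 2. Without the 10 most abundant contigs the differences in the pairs were 0.24 and 0.34, without the 50 most abundant 0.08 and 0.21, and without the 100 most abundant -0.02 and 0.20. With each distinct sequence of all contigs counted once they were 0.127 and 0.108.

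At the level of single sequences, 403 of the 176919 distinct 23-30 nt sequences tested rose and 155 fell (edgeR with the block). Without the block edgeR called 0 (3346 at an unadjusted p of 0.05) and DESeq2 called 0. TMM scaling in the blocked fit left 143 higher and 30 lower, a higher share of 82.7% against 72.2%, and leaving piwi-ctrl 1 out of the blocked fit gave 625 higher and 211 lower. Several of the largest rises were overlapping forms of 1 sequence family. The read CCTCAAAGAACTCCACAAGCACTCGAAA had 50 reads in piwi-embKD 1, 1630 in piwi-embKD 2 and 0 in the other 3 libraries, at least 100.3-fold higher than white-embKD with its floor of 3 reads per library (edgeR with the block, adjusted p = 2.95e-11; DESeq2 with the block, adjusted p = 0.296). That bound rests on piwi-embKD 2: it was 4.79-fold without it, against 196-fold without piwi-embKD 1, 59.1-fold without white-embKD 2 and 331-fold without white-embKD 1. TCGAACTGCACCCTGGATCGGACCCGC had 31 reads in white-embKD 1, 651 in white-embKD 2 and 0 in all 3 libraries with the piwi hairpin, at least 129-fold lower in piwi-embKD (edgeR and DESeq2 with the block, adjusted p = 3.56e-09 and adjusted p = 0.27), a bound of 54.1-fold without white-embKD 2 and 203-fold without white-embKD 1. TCTCATCTTCCAAAATCGACTGACT, with 35 and 377 reads in white-embKD 1 and 2, had 1 read in piwi-ctrl 1 and 0 in piwi-embKD, at least 89.3-fold lower. Floors and intervals cover counting error only, since reads carried no molecular identifiers and may be copies of 1 molecule.

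The sequences that rose differed in base composition from those that fell. Primary piRNAs tend to start with uridine (1U), and piRNAs made by the ping-pong cycle, in which a pair of piRNAs from opposite strands direct each other's cleavage, tend to have adenosine at the tenth base (10A). Of the 403 risen sequences, 109 (27.0%) had 10A without 1U, against 18 of the 155 fallen ones (11.6%; Fisher's exact test, two-sided, p = 6.95e-05) and 12.3% of all sequences tested. 1U was found in 56.3% of risen and 70.3% of fallen sequences (Fisher's exact test, p = 0.00272). With TMM scaling the shares of 10A without 1U were 32.9% and 16.7% (Fisher's exact test, p = 0.0847). They were 24.3% and 12.9% with the block and DESeq2 (Fisher's exact test, p = 0.000207). Without piwi-ctrl 1 in the blocked edgeR fit they were 25.9% and 13.3% (Fisher's exact test, p = 9.46e-05). Overlapping sequences of a locus are not independent, so these p-values are too small.

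In whole libraries the same measures differed in the same direction in both pairs, but an exact permutation test of 2 libraries against 2 cannot give a p below 0.333. The test also ignored the pairing, so the gap between centres counted as spread in it. Reads with 10A and no 1U made up 11.2% of white-embKD 1 and 12.0% of piwi-embKD 1, and 11.9% and 14.9% of the second pair. 1U reads made up 70.3% ± 1.31 in white-embKD and 68.2% ± 2.47 in piwi-embKD (mean ± SD, n = 2; exact permutation test, two-sided, p = 0.667), a difference of -2.04 points that was -0.29 without piwi-embKD 2, -3.79 without piwi-embKD 1 and -1.12 without white-embKD 1. The difference in 10A without 1U, 1.90 points, was 0.447 without piwi-embKD 2, 3.36 without piwi-embKD 1 and 0.88 with distinct sequences. All 5 libraries had the 10 nt overlap between 5′ ends on opposite strands that marks ping-pong. In both-strand contigs at equal depth, 53.7% and 57.3% of reads in pair 1 and 35.6% and 40.8% in pair 2 had such a partner, in white-embKD and piwi-embKD in that order. The group means were 44.7% ± 12.8 and 49.0% ± 11.7 (n = 2; exact permutation test, two-sided, p = 0.667), and piwi-ctrl 1 had 56.1%. The gap between centres was larger than that between groups, and the difference turned to -4.68 points without white-embKD 2 and to -3.93 points without piwi-embKD 1. Of 30 library measures tested, none had an exact p under 0.333 (0.769 after Benjamini-Hochberg adjustment).

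**Figure D3:**
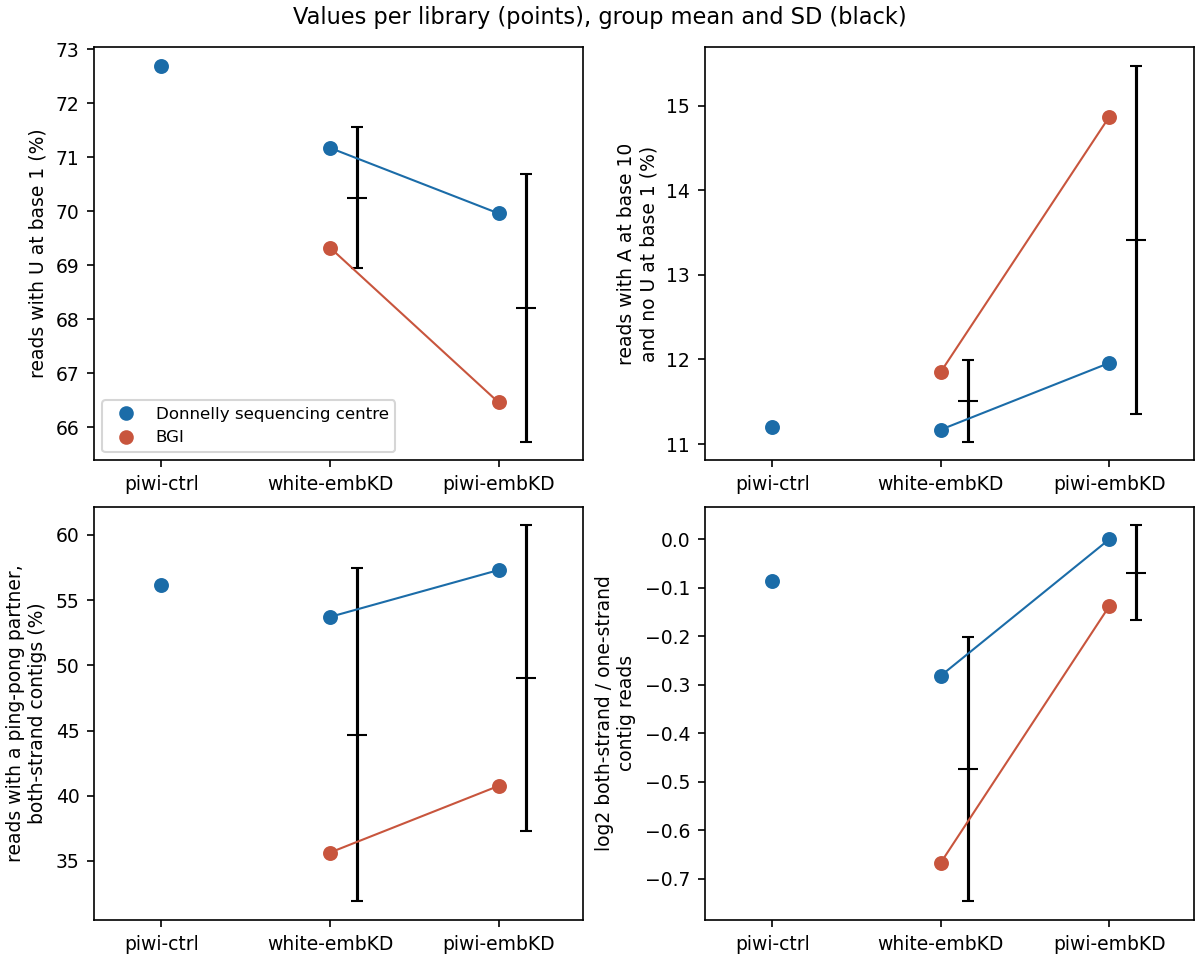
Share of 23-30 nt reads with U at base 1, share with A at base 10 and no U at base 1, share of reads of both-strand contigs with a ping-pong partner (libraries thinned to 3410837 reads), and log2 ratio of both-strand to one-strand contig reads, for each library (points; blue, Donnelly sequencing centre; red, BGI). Black bars are group means and SD (n = 2), lines join same-numbered libraries, vertical axes do not start at 0, and piwi-embKD lies below white-embKD in the first panel and above it in the other panels in both pairs.

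**Figure D4:**
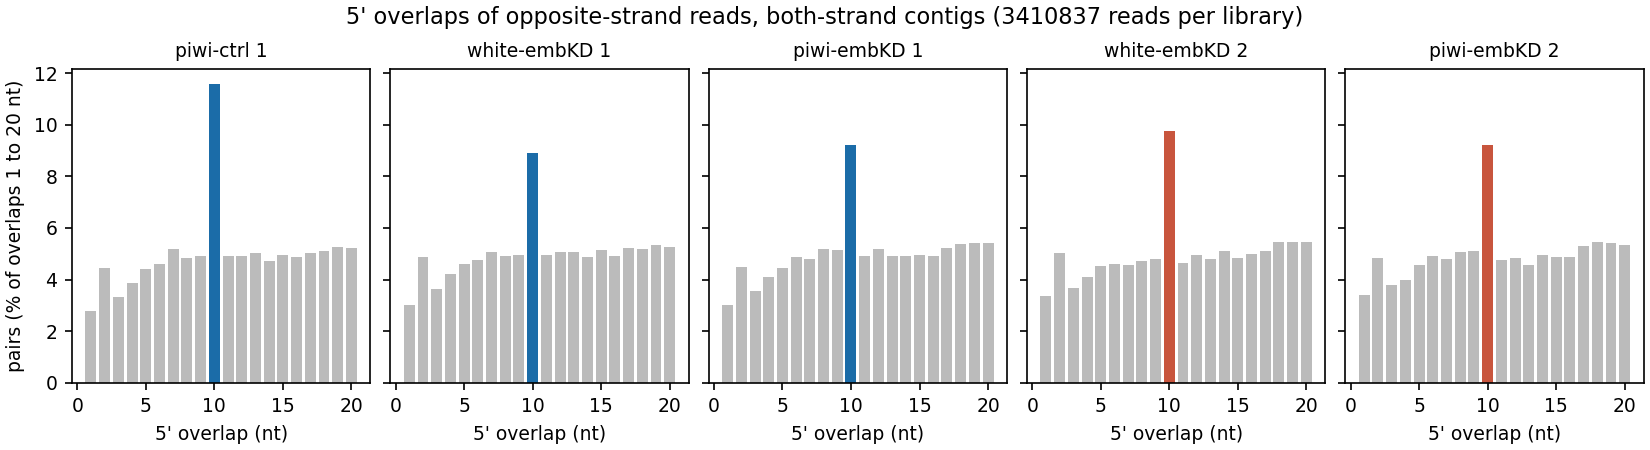
Pairs of 23-30 nt reads from opposite strands of both-strand contigs by the length of their 5′ overlap (horizontal axis, nt), as percent of all pairs with overlaps of 1 to 20 nt, in each library thinned to 3410837 reads. The coloured bar at 10 nt, the ping-pong overlap, is the highest in all 5 libraries.

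The 21 nt reads, candidates for siRNAs, showed no change that passed the edgeR test with all libraries. There were 123099 in piwi-ctrl 1, 124340 in white-embKD 1, 677456 in piwi-embKD 1, 488406 in white-embKD 2 and 816791 in piwi-embKD 2. Per 100 reads of 23-30 nt they stood at 3.65 in white-embKD 1 and 3.37 in piwi-embKD 1, and at 2.56 and 5.09 in the second pair, so the pairs went opposite ways. edgeR called 0 of 7680 distinct sequences without the block (215 at an unadjusted p of 0.05) and 0 with it (262), and DESeq2 called 0 without and 1 with the block. Without piwi-ctrl 1 the blocked edgeR fit called 8 higher and 0 lower. Reads with a partner offset as in a Dicer duplex (19 nt paired) made up 7.38% in white-embKD 1 and 10.4% in piwi-embKD 1, between the 9.39% and 13.2% with an overlap of 18 nt and the 5.91% and 9.64% with 1 of 20 nt. In white-embKD 2 and piwi-embKD 2 the shares were 2.61% and 3.59% for the duplex, 5.33% and 5.88% for 18 nt, and 2.20% and 2.81% for 20 nt.

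The second comparison, piwi-embKD against piwi-ctrl, holds the genotype and differs in the temperature shift, with a single control library that was assumed to vary like the other groups. With the block, 15 contigs were higher and 81 lower in piwi-embKD (edgeR; 0 without the block, with 97 at an unadjusted p of 0.05; DESeq2 34 higher and 23 lower). With TMM scaling these became 86 and 90, a higher share of 48.9% against 15.6%, and the median of all contigs moved from -0.31 to 0.01. With contigs from k-mers of 20 nt, the blocked fit called 0 (300 at an unadjusted p of 0.05), and so it did with contigs of at least 200 nt (95). A set of 7 contigs rose and a set of 30 fell against both white-embKD and piwi-ctrl. Independent lists would share 0.781 and 9.50, but part of the excess may come from the piwi-embKD libraries that both comparisons use. Of the 7 risen contigs 5 were both-strand, and of the 30 fallen ones 21 were, against 877 of all 1671 contigs. Among all calls against piwi-ctrl, 5 both-strand contigs were higher and 48 lower, and 10 one-strand contigs were higher and 33 lower. The higher share of calls was 9.43% and 23.3% (Fisher's exact test, two-sided, p = 0.0899), the reverse order of that against white-embKD. Over all contigs the median log2 fold change was -0.59 for both-strand and -0.35 for one-strand contigs (camera, p = 0.00661 with a preset correlation and p = 0.545 with an estimated correlation; 0.111 and 0.171 with the block). For white-embKD against piwi-ctrl these medians were -0.378 and -0.215 (camera, p = 0.0246 with a preset correlation and p = 0.610 with an estimated correlation; 0.190 and 0.206 with the block). A lower median of both-strand contigs against piwi-ctrl was thus also seen without embryonic piwi depletion.

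Contig 964 (122 nt, both-strand) had 23.6 RPM in piwi-ctrl 1, 42.8 ± 9.13 in white-embKD and 174.9 ± 12.3 in piwi-embKD (n = 2 each), and a log2 fold change of 3.03 ± 0.42 against piwi-ctrl (SE; edgeR with the block, adjusted p = 0.0254). Contig 445 stood at 105.5 RPM in piwi-ctrl 1, near its level in white-embKD, and contig 569 at 74.4 RPM, which gave log2 fold changes of 2.29 ± 0.38 and 2.92 ± 0.39 against piwi-ctrl (adjusted p = 0.0308 and 0.0254). Contig 101 (122 nt, one-strand) rose to 1735 ± 174 RPM (n = 2) from 583.9 in piwi-ctrl 1 and 492.1 ± 203 in white-embKD (n = 2). Among the fallen, contig 481 (148 nt, one-strand) had 275.4 RPM in piwi-ctrl 1, 331.7 ± 145 in white-embKD and 115.3 ± 92.8 in piwi-embKD (n = 2 each). Contig 289 (396 nt, 49.1% minor strand) had 647 RPM in piwi-ctrl 1, 419.8 ± 22.4 in white-embKD and 203.2 ± 26.8 in piwi-embKD (n = 2 each). Contigs 101, 481 and 289 are examples picked after their values were seen.

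The position of piwi-ctrl 1 was compared with the replicate 1 libraries of the same centre over features chosen on the other pair alone (a log2 ratio of piwi-embKD 2 to white-embKD 2 beyond 1 or -1), since calls rest in part on the replicate 1 libraries themselves. For sequences, piwi-ctrl 1 lay nearer white-embKD 1 than piwi-embKD 1 in 54.8% of the 40322 higher and 45.3% of the 43812 lower ones, against 47.1% of all 176919. The median log2 ratio of piwi-embKD 1 to white-embKD 1 was 0.58 for these higher and -0.01 for these lower sequences. The lower ones thus showed no fall in pair 1 against which piwi-ctrl 1 could be placed. The libraries piwi-ctrl 1 and white-embKD 1 also had the fewest reads, which can draw them together at low counts. For contigs, piwi-ctrl 1 lay nearer white-embKD 1 in 52.3% of the 107 higher (exact binomial 95% interval 42.5 to 62.1) and 67.2% of the 247 lower ones (61.0 to 73.0), against 53.0% of all 1671. Over the 356 contigs within 0.2 log2 in the other pair, the median log2 ratio of piwi-ctrl 1 to white-embKD 1 was 0.19. That of piwi-embKD 1 to piwi-ctrl 1 was -0.14 over the same contigs, and such a shift of piwi-ctrl 1 in RPM bears on these shares. Among the 10 sequences with the largest falls, TGTCTGTCGTACGCGTTATTCGCTGA had 33 reads in piwi-ctrl 1, 15 and 88 in white-embKD 1 and 2 and 0 in piwi-embKD. A count of 0 in piwi-ctrl 1 allows up to 0.736 RPM.

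The third comparison, white-embKD against piwi-ctrl, sets the controls against each other and covers the differences of hairpin and temperature with no embryonic piwi depletion. With the block, 3 contigs were higher and 11 lower in white-embKD (edgeR; 0 without the block, with 45 at an unadjusted p of 0.05; DESeq2 12 and 13). With contigs from k-mers of 20 nt or of at least 200 nt alone, the blocked fit called 0 (220 and 75 at an unadjusted p of 0.05). With TMM scaling these became 49 and 65, a higher share of 43.0% against 21.4%, and the median of all contigs moved from -0.17 to 0.02. The 3 higher contigs, numbers 196, 996 and 1455, were all one-strand and rarest in piwi-ctrl 1. Contig 196 had 119.3 RPM there, 587.7 ± 58.2 in white-embKD and 746.9 ± 150 in piwi-embKD (n = 2 each), and contig 996 had 13.3, 98.7 ± 86.0 and 105.4 ± 94.4 RPM in the same order. Contig 552 (129 nt, one-strand) went the other way, with 608.7 RPM in piwi-ctrl 1, 98.5 ± 59.2 in white-embKD and 94.8 ± 68.2 in piwi-embKD (n = 2 each; log2 fold change of white-embKD to piwi-ctrl -2.04 ± 0.35, edgeR with the block, adjusted p = 0.0473). Contig 552 was picked after its values were seen. Of the distinct sequences, 69 were higher and 43 lower in piwi-embKD than in piwi-ctrl, and 7 higher and 13 lower in white-embKD than in piwi-ctrl (edgeR with the block; 0 without it, with 0.233% and 0.488% of sequences at an unadjusted p of 0.05; DESeq2 2 and 2). With TMM scaling those splits were 12 and 3, and 2 and 1.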

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

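The replicate block, DESeq2, TMM scaling, the low-count filter, leaving out libraries and alternatives for library values were planned before the data were seen. Alternative fits of contigs and 21 nt sequences, and the block with TMM or DESeq2, were chosen after the data were seen. The numbers pair the samples by sequencing centre, and the replicate block moved the counts of changed contigs from 0 in all 3 comparisons of edgeR to 283 (piwi-embKD against white-embKD), 96 (piwi-embKD against piwi-ctrl) and 14 (white-embKD against piwi-ctrl). In the same order the counts were 409, 176 and 114 with the block and TMM scaling, 360, 140 and 83 with the block and DESeq2, 521, 396 and 187 with the block and distinct sequences, and 88, 57 and 25 with DESeq2 without the block. With the block and a k-mer weight of at least 0.5 they were 240, 99 and 34. With the block and k-mers of 20 nt they were 181, 0 and 0 (449, 300 and 220 at an unadjusted p of 0.05), and with the block and contigs of at least 200 nt 0 in each (169, 95 and 75). The cause of the last 2 sets of counts of 0 was not tested. TMM scaling without the block and the same assemblies without the block called 0 contigs by edgeR. Leaving out 1 library of the fit without the block gave 0 to 2 contigs for piwi-embKD against white-embKD (2 without white-embKD 2 and without piwi-embKD 2, 1 without piwi-embKD 1), 0 to 1 for piwi-embKD against piwi-ctrl (1 without piwi-embKD 1 and without white-embKD 2) and 0 for white-embKD against piwi-ctrl. A lone library left in a group was assumed to vary like the other groups, and the blocked fit has no residual degrees of freedom once a knockdown library is left out. Without piwi-ctrl 1 it called 290 contigs for piwi-embKD against white-embKD, with 86 of the 87 higher and 196 of the 196 lower calls among them.

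Distinct 23-30 nt sequences changed numbered 558, 112 and 20 with the replicate block, 173, 15 and 3 with the block and TMM scaling, 786, 191 and 46 with the block and DESeq2, and 0, 2 and 2 with DESeq2 alone. The first of these was 836 with the block and without piwi-ctrl 1. Leaving out a knockdown library, or the filter, gave 0 by edgeR without the block. Among 21 nt sequences the block with DESeq2 called 1 for piwi-embKD against white-embKD, the block without piwi-ctrl 1 called 8, and all other fits 0.

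Leaving out each library moved the difference in reads with a ping-pong partner (piwi-embKD minus white-embKD) over -4.68 to 13.4 points in both-strand contigs, below 0 without white-embKD 2 or piwi-embKD 1, and over -0.739 to 11.9 points in one-strand contigs, below 0 without white-embKD 2. The ping-pong z-score difference of both-strand contigs, -0.427, ranged over -1.50 to 0.645, above 0 without white-embKD 2 or piwi-embKD 1, and was 0.238 with distinct sequences. The difference of medians between strand classes ranged over -0.29 to 0.023, above 0 without white-embKD 1. The cause of these reversals was not tested, beyond the gap between centres that a missing library leaves unbalanced. The log2 fold change of contig 1 without the block ranged over -0.68 to 1.77, below 0 without white-embKD 1 or piwi-embKD 2. That of contig 5 ranged over -0.59 to 0.51, above 0 without piwi-embKD 1 or white-embKD 2, and was 0.078 with the block and TMM scaling and 0.083 with the block and DESeq2. That of contig 7 ranged over -0.36 to 1.41 and that of contig 9 over -0.069 to 4.95, both below 0 without piwi-embKD 2. Of the 31 contigs named, 24 passed the threshold with the block, 27 with the block and TMM scaling, 25 with the block and DESeq2 and 15 with DESeq2. Of the 21 sequences named, 21 passed it with the block, 13 with the block and TMM scaling and 12 with the block and DESeq2. Some differences kept direction, not size, with distinct sequences and without each library. 1U (-2.04 points) spanned -3.79 to -0.29, 10A (2.06) 0.537 (distinct sequences) to 2.65 and 10A without 1U (1.90) 0.447 to 3.36. The log2 ratio of both-strand to one-strand reads (0.405) spanned 0.118 to 0.598. Read length (-0.215 nt, -0.402 to -0.0276) went opposite ways in pairs 1 and 2 (0.0732 and -0.503).

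The alternatives planned for clusters, transposon families, windows and genes (scaling to the flamenco cluster, uniquely placed or split reads, window thresholds) were not run, since no genome sequence was used here. For contigs, dropping the low-count filter removes nothing and tests nothing. Depth was smallest in white-embKD 1 and piwi-ctrl 1, where 0 reads of a sequence allow up to 0.88 and 0.736 RPM.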

Other observations

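All tests in this part were chosen after the results were seen, apart from the tests of 10A on sets matched on abundance and with 1 sequence per contig, and the values of the first 2 paragraphs were not planned.

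Sequences present in both piwi-embKD libraries (at least 5 reads at equal depth) and in no other library numbered 361. Those present in both white-embKD libraries and in no other numbered 91, and the remaining pairs of 1 library from each centre held 36, 61, 52 and 43. Pairs from the same centre held 1091 (white-embKD 2 and piwi-embKD 2), 619 (piwi-ctrl 1 and white-embKD 1), 435 (piwi-ctrl 1 and piwi-embKD 1) and 344 (white-embKD 1 and piwi-embKD 1). Many of the 361 may be variants of a few loci, as in the largest rises: TTTTAAAAGAACTCACTAAGGCCC (46 and 288 reads in piwi-embKD 1 and 2, 0 elsewhere) is the end of TGAATTTTAAAAGAACTCACTAAGGCCC (405 and 135 reads, 1 in piwi-ctrl 1 and 0 in white-embKD). The 229 risen sequences on contigs lay on 64 contigs, and with 1 sequence per contig 15 of the 64 (23.4%) had 10A without 1U. As given below, that share cannot exclude that a few loci account for the excess.

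Tested apart, the minor strands of contigs gave 97 higher and 122 lower in piwi-embKD than in white-embKD, and the major strands 46 and 101 (edgeR with the block; 0 and 0 without it, with 61 and 53 at an unadjusted p of 0.05). In both-strand contigs 10A was found in 37.2% of minor-strand reads of white-embKD 1 and 40.8% of piwi-embKD 1, and in 39.9% and 44.9% of the second pair (group means 38.6% ± 1.94 and 42.9% ± 2.91, n = 2; exact permutation test, two-sided, p = 0.333, the smallest possible). The rise was not particular to that strand: major-strand shares were 31.6% and 33.0% in pair 1 and 30.0% and 37.7% in pair 2 (exact permutation test, two-sided, p = 0.333). With distinct sequences the differences in the pairs were 0.0369 and 1.51 points on the minor strand, and -0.158 and 1.15 on the major strand. Reads ending in CCT, the most frequent last 3 bases of 23-30 nt reads in all 5 libraries, made up 5.80%, 7.27% and 6.76% of piwi-ctrl 1, white-embKD 1 and piwi-embKD 1, and 11.3% and 12.6% of white-embKD 2 and piwi-embKD 2.

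The first pattern is the set of 283 contigs that differed between piwi-embKD and white-embKD with the block. Copies of a few molecules account for it poorly, since 248 of the 283 were also called in the same direction when each distinct sequence counted once, and so does scaling, since 282 were called with TMM factors. Genotype background stays open: over contigs chosen on the BGI pair alone, the median log2 ratio of piwi-embKD 1 to piwi-ctrl 1, which share a genotype, was 0.33 (bootstrap interval over contigs 0.06 to 0.56) for 107 higher contigs and -0.82 (-0.91 to -0.71) for 247 lower ones, against -0.14 (-0.19 to -0.08) for 356 unchanged ones. That of piwi-ctrl 1 to white-embKD 1 was 0.50 (0.38 to 0.66), -0.06 (-0.16 to 0.06) and 0.19 (0.13 to 0.29), so piwi-ctrl 1 lay between the 2 for the higher contigs and near white-embKD 1 for the lower ones. The unchanged contigs were shifted as well, and TMM factors were 1.29 in piwi-ctrl 1, 1.12 in white-embKD 1 and 1.055 in piwi-embKD 1. Such a shift of piwi-ctrl 1 in RPM may make rises and falls look unlike, so no difference in their link to genotype is shown. Since piwi-ctrl is 1 library that also differs in temperature, genotype and the shift in embryos cannot be told apart. Differences between crosses or stocks were not tested.

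The second pattern is the excess of 10A without 1U among the sequences that rose in piwi-embKD. Selection of abundant sequences does not account for it: the observed 27.0% stood at the 100th percentile of 10000 sets of tested sequences matched on abundance, whose mean was 11.1% and highest 17.1%. With 1 sequence per contig, the one with the smallest p, 15 of 64 contigs (23.4%, exact binomial interval 13.8 to 35.7) had such a sequence, against 12.3% of all tested sequences. With the 174 sequences off contigs included, 36 of 159 families that share a contig or 18 nt did (22.6%, 16.4 to 29.9). All tested sequences were not reduced in the same way, so this cannot exclude that many sequences from a few loci account for the excess. A candidate explanation, not tested here, is a larger share of secondary, ping-pong-made piRNAs among the sequences higher in piwi-embKD than in white-embKD. The whole-library ping-pong values neither show nor exclude it, and genotype background stays open for these sequences as well. The explanation by ping-pong is weakened by 10A as a whole against piwi-ctrl, found in 47.8% of 69 higher and 53.5% of 43 lower sequences. 10A without 1U made up 33.3% and 20.9% of them, against 12.3% of all tested (Fisher's exact test against the other sequences, p = 4.70e-06 and p = 0.100). With TMM factors the shares of 10A without 1U were 32.9% and 16.7% for 143 risen and 30 fallen sequences (Fisher's exact test, p = 0.0847). The gap was thus kept, with fewer sequences to test it. Overlapping sequences make these p-values too small.

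The third pattern is the higher ratio of both-strand to one-strand reads in piwi-embKD, 0.41 on the log2 scale over the pairs but 0.118 with each distinct sequence counted once. Leaving out the 10 most abundant contigs, contigs 3 and 4 among them, left 71.5% of it, and leaving out the 100 most abundant left 21.7%, so the 100 most abundant contigs may carry most of the pattern. Whether both-strand contigs moved as a class stays open: the difference of medians between the classes in the blocked fit was -0.19, with a bootstrap interval over contigs (-0.29 to -0.11) that leaves out the spread between libraries, and camera gave p = 0.684 with a preset correlation and p = 0.525 with an estimated correlation. In the fit without the block the difference was 0.02 when white-embKD 1 was left out. Both-strand contigs are not genomic dual-strand clusters, so this says nothing on annotated clusters.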
